A study of Mus musculus with 30 samples.

How the data were processed

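RNA of the mouse hindbrain was measured on 30 Illumina bead arrays, 1 array per sample. Per the labels' protocols, adult mice (6 to 12 weeks) were kept at 30 °C, and received lipopolysaccharide (LPS, 100 ug per kg), a bacterial cell wall component that causes fever, or its vehicle, sterile PBS. The protocol gives a mean fever of 2.175 °C (SD 1.18) when the mice were killed, without naming the groups it covers. Polysome-bound RNA was obtained by translating ribosome affinity purification (TRAP) from mice that carry a ribosomal protein tagged with EGFP in cells expressing Slc6a2 (the noradrenaline transporter) or Slc6a4 (the serotonin transporter). Total RNA came from the lysate before the precipitation (Pre-IP) or after it (Unbound), and the labels' protocol pools both. The RNA was amplified in 2 batches. In TRAP RNA the batches cut across line, sex and treatment. Every Pre-IP array was in batch 1 and every Unbound array in batch 2, so the batch and the kind of total RNA cannot be told apart.

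The authors deposited 1 table of 45281 probes with an intensity and a detection p-value per array. The deposited intensity values were neither normalized between arrays nor background-subtracted, as judged from the file and its values, and ran from 8.2 to 60960. The deposited detection p-value moves in steps that imply 936 negative control probes. The submitters' processing notes name lumi without a version or a role. Scanner software and bead summarisation are not given in the sources used here. No 2 columns held identical values.

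The file pairs no probe with a gene, and 0 probe IDs occurred in the gene table at hand. Probes are therefore reported by ID, all probes were tested as separate features, and at most 2 IDs per direction are named for a comparison. The 31 gene lists fixed before the data were examined could not be tested for this reason, and the named genes of the plan could not be looked up.

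Intensities were corrected with normexp using the detection p, quantile normalized over all 30 arrays with an offset of 16 and put on the log2 scale (neqc of limma 3.58.1 in R 4.3.3). A probe was kept where its detection p was under 0.01 on at least 3 arrays of the fit, which left 26312 probes for fits of all arrays, 21863 for the 15 TRAP arrays and 24914 for the 15 total RNA arrays. On no array were 14692 probes detected. Each fit had 1 mean per line, fraction, sex and treatment (16 groups over all arrays) and a term for the amplification batch within each fraction. Contrasts gave equal weight to the other groups and to both batches. lmFit and eBayes with a trend gave p-values, adjusted by Benjamini-Hochberg, with 0.05 as the threshold. Residual degrees of freedom were 12 for all arrays, 6 for TRAP and 6 for total RNA, and these numbers limit the precision. A TRAP fit of 1 line alone had fewer, and its recovery of simulated changes was not examined. Comparisons within TRAP used the 15 TRAP arrays of both lines, which share 1 estimate of the spread. As the lines differ in spread, this can make tests within Slc6a2 TRAP too lenient and within Slc6a4 TRAP too strict. Simulated data with no change had the spread of each line and the same batch shift in both lines. Batch shifts that differ between the lines were not simulated. At an unadjusted p under 0.05 the simulated data held a mean of 1738 probes for sex and 1727 for LPS in Slc6a2 TRAP. In Slc6a4 TRAP the means were 508 and 514, against 1093 expected in either line. After adjustment at most 1 probe passed in any of the 20 simulations.

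Named probes were, by a rule fixed before the data were examined, those with the largest called rise and fall whose difference had the same sign in both batches, here limited to 2 per direction. Where fewer than 4 probes passed, those with the smallest p are given as values. Where a probe was detected on no array of 1 group, the fold is a bound. It sets the mean of the brighter group against the mean, per array, of the higher of the dim probe's value and the lowest value among detected probes.

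The design text names 16 mice, so TRAP and total RNA of 1 line, sex, treatment and batch were taken to be from 1 mouse. Across probes, deviations of such pairs from the mean of their line, fraction and batch correlated at a mean of 0.064 (14 pairs). Such pairs also share sex and treatment, so this value cannot show that they share a mouse. For other pairs of the same line and batch it was -0.021 (42 pairs), a value that follows largely from taking out that mean. The batch number is a label that marks shared handling. Arrays of different lines correlated in their deviations at a mean of 0.050 within a TRAP batch and -0.048 between batches, and at 0.12 and -0.12 in total RNA. These deviations were taken from the mean over both batches. The value between batches is therefore close to the negative of the one within and adds nothing to it.

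The fits were tested on simulated data with the measured spread of each line and, per comparison, 100 probes changed by 1 log2 unit and 100 by 2. Of changes of 2 log2 units, 89% were recovered for Slc6a2 TRAP against total RNA, 61% between the lines, 54% for sex in Slc6a2 TRAP, 37% for sex in Slc6a4 TRAP, 47% and 42% for LPS in both TRAP sets, and 95% for LPS in total RNA. Of 1 log2 unit, 18% were recovered for sex in Slc6a2 TRAP. For the response to LPS by sex in Slc6a2 TRAP, 10% of changes of 2 log2 units were recovered. For a sex difference or an LPS response that differs between the lines, 21% and 22% were recovered. For a sex difference (Slc6a2 line) or an LPS response (both lines) that differs between TRAP and total RNA, it was 44% and 68%. Unchanged probes called in these simulations numbered 14 for sex in Slc6a2 TRAP, 8 for LPS in Slc6a2 TRAP, 0 for either in Slc6a4 TRAP, and 22 and 13 for TRAP against total RNA in the Slc6a2 and Slc6a4 line.

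Alternatives covered background correction, normalization, the probe filter, the batch term, array weights, the mouse as a random block, single batches, an additive model, a spread shared by all arrays, each line fitted alone, testing TRAP-enriched probes alone, and leaving out each array in turn. Leaving out an array kept the joint normalization. Sample titles end in a letter from A to F and a position. The labels do not say what the letter stands for, and it may be the slide. Letter A held 6 Slc6a2 TRAP arrays, B 5 Slc6a4 TRAP arrays, C 2 of each, D 6 Slc6a2 total RNA arrays, E 6 Slc6a4 total RNA arrays and F 1 and 2 of these. No letter held both TRAP and total RNA, and line goes with the letter except within C and F. The fits do not account for the letter. As alternatives it was used as a random block, as a term (in total RNA within the additive model), and by fitting the arrays of 1 letter alone. On simulated data with a shift per letter and changes of 2 log2 units, the fit with the letter as a term recovered 0% of changes between the lines (0% also within letter C), 32.5% for sex and 31.5% for LPS in Slc6a2 TRAP, and 90% and 95% for sex and LPS in total RNA.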

Results

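The series asks how noradrenergic neurons of the mouse brainstem differ between the sexes, with serotonergic neurons and whole hindbrain RNA beside them. It holds 8 TRAP arrays of the Slc6a2 line, 7 TRAP arrays of the Slc6a4 line, 7 total RNA arrays of the Slc6a2 line and 8 of the Slc6a4 line. Each line, fraction, sex and treatment had 2 arrays, except Slc6a4 TRAP of PBS males and Slc6a2 total RNA of LPS males with 1 each. Between 15432 and 19424 probes were detected per TRAP array and between 20395 and 23122 per total RNA array. The first principal component, with 31.9% of the variance, separated TRAP from total RNA, and the second, with 9.9%, separated the lines among TRAP arrays. Slc6a2 TRAP arrays resembled each other less (median r across probes 0.87) than Slc6a4 TRAP arrays did (median r 0.95). Their median residual SD was 0.56 log2 units, against 0.37 in Slc6a4 TRAP. The Slc6a2 TRAP array of the PBS male in batch 2 stood apart, at 116 on the third component (6.38% of the variance), where the other batch 2 arrays of its set lay from 17.3 to 26.5, and had the fewest probes detected. Without it the median r of Slc6a2 TRAP was 0.87 and the median residual SD 0.49, against 0.36 in Slc6a4 TRAP, and the counts for sex, for LPS and for the LPS response by sex in Slc6a2 TRAP were 4, 30 and 5.

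**Figure D1:**
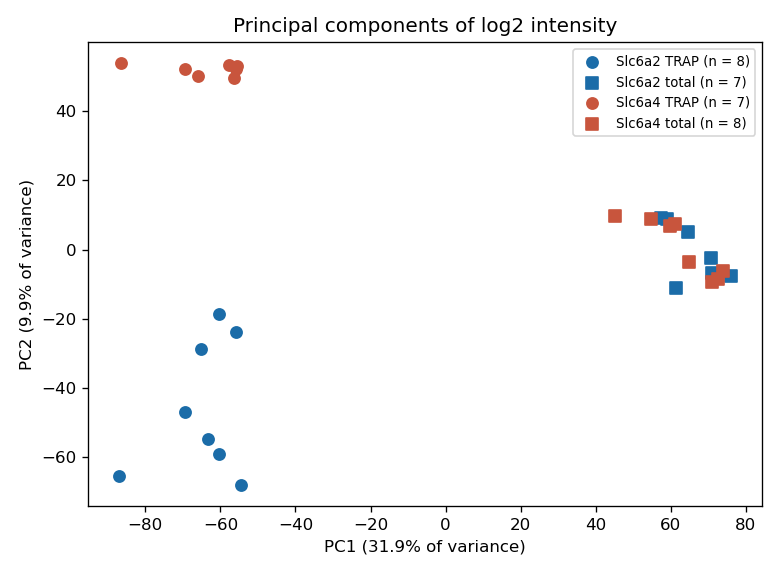
First against second principal component of normalised log2 intensity, 1 point per array, coloured by line, with circles for TRAP and squares for total RNA. TRAP and total RNA lie apart on the first component (31.9% of the variance), and the lines lie apart on the second (9.9%) among TRAP arrays.

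Precipitation of tagged ribosomes asks which transcripts a neuron type holds above the whole hindbrain. In the Slc6a2 line 5164 probes were higher and 6229 lower in TRAP than in total RNA, of 26312 tested. ILMN_1238982 was higher by 6.48 log2 units (SE 0.36, adjusted p = 3.4e-10), at 11.57 ± 0.22 (SD, n = 8) against 5.12 ± 0.73 (SD, n = 7, 3 detected). ILMN_2669234 was detected on all 8 TRAP arrays and on 0 of 7 total RNA arrays, and was at least 50.9-fold higher in TRAP (adjusted p = 6.4e-13). ILMN_2580825, detected on 1 of 8 TRAP arrays, fell by 4.28 log2 units (SE 0.42) and ILMN_1239776, detected on 6 of 8, by 4.09 (SE 0.48). Within batch 1 and batch 2, ILMN_1238982 differed by 6.05 and 6.81 log2 units. The share of higher probes among those called was 45.3%, and it was 18.1% when TRAP and total RNA were normalised separately and 35.0% with median centring, and without the filter on dim probes it was 54.4% (7255 higher and 6078 lower), so the balance of rises and falls depends on the scaling and on the filter. The median over all probes was -0.077 as fitted, -0.49 with separate normalisation, -0.23 with median centring and 0.061 without the filter. No letter of the sample titles, a possible slide, held both TRAP and total RNA, so the letter cannot be told apart from the fraction.

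In the Slc6a4 line 5411 probes were higher and 5579 lower in TRAP than in total RNA. ILMN_2729817 was higher by 6.32 log2 units (SE 0.34, adjusted p = 1.8e-10), at 11.59 ± 0.20 (SD, n = 7) against 5.27 ± 0.50 (SD, n = 8, 4 detected). ILMN_2744603, detected on 6 of 8 total RNA arrays, was higher by 5.98 log2 units (SE 0.27). ILMN_2504686 fell by 4.49 log2 units (SE 0.13), to 8.05 ± 0.41 (SD, n = 7) from 12.56 ± 0.21 (SD, n = 8), and ILMN_2436634, detected on 6 of 7 TRAP arrays, fell by 4.41 (SE 0.31). The share of higher probes was 49.2%, 19.6% with separate normalisation and 55.2% without the filter on dim probes (6543 higher and 5310 lower). Both lines shared 3386 higher probes, against 1062 if the lists were independent, and 3762 lower probes, against 1321. These lists come from 1 fit with a shared spread and batch term. With each line fitted alone, which leaves the joint normalisation in common, 2837 higher probes were shared, against 974 if independent, and 3446 lower probes, against 1357, of 23316 tested in both. In opposite directions 210 probes were called. Batch 1 alone called 2349 probes in the Slc6a2 line and 2689 in the Slc6a4 line.

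The direct comparison of both neuron types found 750 probes higher in Slc6a2 TRAP and 1128 higher in Slc6a4 TRAP, of 21863 tested. ILMN_2922875 was higher in Slc6a2 TRAP by 7.00 log2 units (SE 0.28, adjusted p = 9.9e-08), at 12.76 ± 0.24 (SD, n = 8) against 5.76 ± 0.74 (SD, n = 7, 4 detected). ILMN_2669234 was detected on 0 of 7 Slc6a4 TRAP arrays and was at least 32.8-fold higher in Slc6a2 TRAP. ILMN_2729817 was lower in Slc6a2 TRAP, with a log2 difference of -6.63 (SE 0.38), and ILMN_2713714 with one of -6.33 (SE 0.24), each detected on 1 of 8 Slc6a2 TRAP arrays, so these sizes are set against levels near background. In batch 1 and batch 2 the difference of ILMN_2922875 was 7.43 and 6.80. Of the 750 probes higher in Slc6a2 TRAP, 440 were also higher in Slc6a2 TRAP than in total RNA and 117 in Slc6a4 TRAP. Of the 1128 higher in Slc6a4 TRAP, 733 were higher than total RNA there and 254 in Slc6a2 TRAP. These counts share the TRAP arrays. With line probes taken from batch 1 and enrichment from batch 2, 35 of 43 probes higher in Slc6a2 TRAP (81.4%) were enriched over total RNA in that line and 5 in the other, and 26 of 28 higher in Slc6a4 TRAP (92.9%) were enriched there, against 18% of all probes in either line. With the batches exchanged these were 127 of 376 (33.8%) and 150 of 593 (25.3%), against 4.23% and 4.70% of all probes. In the other line 30 (7.98%) and 35 (5.90%) of them were enriched. All probes here include those detected in total RNA alone, which can lower the share set against the line probes. Without 1 Slc6a4 TRAP array of batch 1 the count was 1154 (LPS female), 1187 (LPS male) or 1205 (PBS female), and it was 72 in batch 1 alone (44 higher and 28 lower in Slc6a2 TRAP, the opposite balance) and 988 in batch 2 alone (384 and 604). Line goes with the letter in the sample titles, a possible slide, except for the 4 TRAP arrays of letter C. With the letter as a term 54 probes passed (30 higher and 24 lower), and within letter C 86 did (41 and 45). Across probes, which are not independent replicates, the line difference within letter C correlated with that of the other TRAP arrays at r = 0.49 and rho = 0.38, and ILMN_2922875 differed by 7.26 log2 units within letter C.

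The sex comparison found few probes in either neuron type. In Slc6a2 TRAP 1 of 21863 probes passed. ILMN_1215914 was lower in females, at 5.57 ± 0.31 (SD, n = 4) and undetected on all 4 arrays, against 9.34 ± 0.38 in males (SD, n = 4), at least 10.2-fold (adjusted p = 0.010). ILMN_1241001 was undetected on all 4 female arrays and stood at 8.27 ± 0.97 in males (SD, n = 4), at least 4.88-fold apart, with an adjusted p of 0.056 by limma, above the threshold. ILMN_2726905 had a female minus male difference of 1.58 (SE 0.20, limma adjusted p = 0.056) and ILMN_2707298 one of 0.66 (SE 0.10, limma adjusted p = 0.11). At an unadjusted p under 0.05 there were 2268 probes, against a mean of 1738 (1652 to 1824) in simulated data with no sex difference, and across probes the sex differences of both batches correlated at r = 0.027 and rho = 0.026, where probes are not independent replicates. Among Slc6a2 TRAP arrays the count was 61 without the PBS male of batch 1, 18 without the PBS female of batch 2, 4 without the PBS or the LPS male of batch 2, 3 without the PBS female of batch 1 and 0 without the LPS female of batch 2. It was also 0 without the Slc6a4 TRAP array of the LPS male in batch 1, with array weights, with the title letter as a term, within letter A, and when the line was fitted alone, where ILMN_1215914 had an adjusted p of 0.51 (9.6e-06 to 0.88 over its alternatives). The fit of the line alone has few residual degrees of freedom, so a count of 0 there says little. Among probes detected on every array of a fraction, and among those enriched in TRAP, 1 probe passed, ILMN_2726905, which was higher in females (adjusted p = 0.047 and 0.039). Its male arrays were at 9.11 ± 1.82 (SD, n = 4), from 7.31 to 10.72, and overlapped the females, from 9.99 to 10.98. The same probe was called for LPS in Slc6a2 TRAP, 1.80 log2 units higher after LPS (limma adjusted p = 0.034). Its difference therefore does not separate the sexes on every array.

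In Slc6a4 TRAP 2 probes passed, both lower in females. ILMN_1241001 was at 4.48 ± 0.09 (SD, n = 4) in females and 8.82 ± 0.15 (SD, n = 3) in males, at least 6.67-fold (adjusted p = 0.045). ILMN_1215914 was lower by at least 11.3-fold (adjusted p = 0.012). ILMN_2738310 stood at 6.53 ± 0.82 in females (SD, n = 4, 2 detected) and was detected on 0 of 3 male arrays, at least 1.49-fold apart, and ILMN_2918875, detected on 1 of 3 male arrays, had a female minus male difference of 2.95 (SE 0.79). Neither passed (limma adjusted p of 1 for both). At an unadjusted p under 0.05 there were 90 probes, against a mean of 508 (456 to 548) in simulated data with no sex difference. No probe of 21863 passed for a sex difference that itself differed between the lines (limma, 894 at an unadjusted p under 0.05). That test recovered 21% of simulated changes of 2 log2 units, so it does not show that the lines are alike. With any 1 of the 7 Slc6a4 TRAP arrays left out, with the line fitted alone, with the title letter as a term or within letter B, 0 probes passed for sex in Slc6a4 TRAP, and 1 passed without any 1 of the 4 female Slc6a2 TRAP arrays. Without the Slc6a2 TRAP array of the PBS male in batch 1, 2 probes differed in their sex difference between the lines, and 1 did without that of the PBS female in batch 1.

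In total RNA, the whole hindbrain reference, 2 probes were higher and 6 lower in females, of 24914. ILMN_1241001 was lower by at least 14.0-fold, at 4.48 ± 0.04 (SD, n = 8) against 9.17 ± 0.43 (SD, n = 7), with an adjusted p of 4.8e-07. ILMN_1235995 was lower by at least 10.1-fold. ILMN_3022688 was higher in females by at least 3.37-fold and ILMN_3123341 by at least 2.30-fold, and neither was detected in males. For ILMN_1241001 the highest female array, over both batches, was at 4.54 and the lowest male array at 8.44. All 8 probes had the same sign in both TRAP sets. Adjusted over the list alone, 4 passed in Slc6a2 TRAP and 5 in Slc6a4 TRAP, against 1 and 2 over all probes, and with each line fitted alone 3 of 5 tested and 5 of 7 did. No probe passed for a sex difference that differed between TRAP and total RNA in the Slc6a2 line (limma, 1734 at an unadjusted p under 0.05, with 44% of simulated changes of 2 log2 units recovered). That count was 37 without the Slc6a2 TRAP array of the PBS female in batch 2, 32 without that of the PBS male in batch 1, and from 1 to 4 without any of the TRAP arrays of the LPS female in batch 2, the LPS males and the PBS female in batch 1 or the total RNA arrays of the PBS male in batch 1 and the LPS male in batch 2. Without the Slc6a2 total RNA array of the PBS male in batch 1, 17 probes differed between the sexes in total RNA, and within letter D and letter E of the titles 0 and 3 did.

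**Figure D2:**
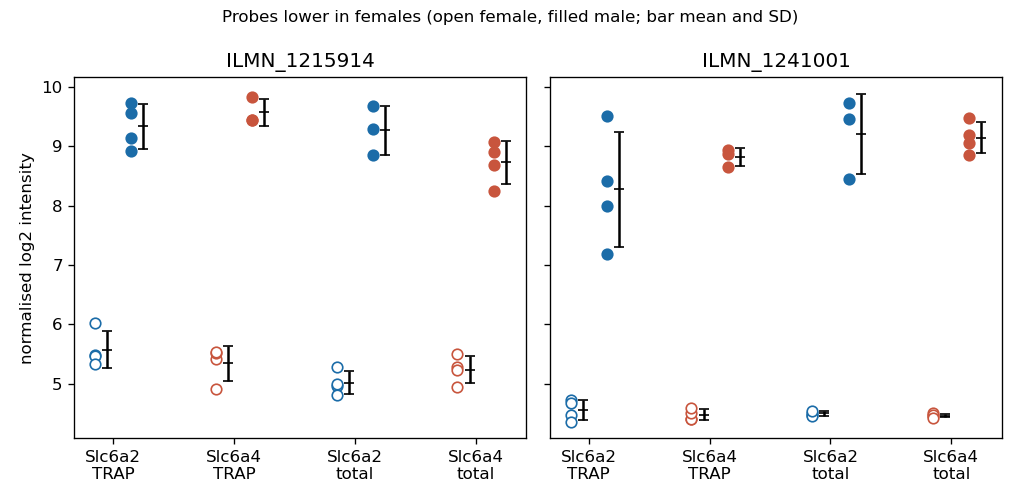
Normalised log2 intensity of ILMN_1215914 and ILMN_1241001 on each array, by line and fraction, with open points for females, filled points for males, and the mean and SD beside them. All female arrays lie below all male arrays for both probes.

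For LPS in Slc6a2 TRAP 11 probes passed as higher and 5 as lower, of 21863. Chance was not excluded for this count. The test recovered 47% of simulated changes of 2 log2 units, so the count does not show a small response. ILMN_2634083 was higher after LPS by 3.83 log2 units (SE 0.50, adjusted p = 0.035), at 10.81 ± 0.14 (SD, n = 4) against 6.98 ± 0.98 (SD, n = 4, 3 detected). ILMN_2846775 was higher by 3.37 (SE 0.45). ILMN_2590605 fell by 2.72 (SE 0.36) and ILMN_1230668 fell by 2.71 (SE 0.38), each to levels detected on 1 of 4 LPS arrays. In batch 1 and batch 2 the difference of ILMN_2634083 was 3.79 and 3.87. At an unadjusted p under 0.05 there were 2262 probes, against a mean of 1727 in simulated data with no change. The count was 0 with the line fitted alone, with array weights, with the title letter as a term or within letter A. It was 51 without the PBS male of batch 1, 30 without the PBS male of batch 2, at most 2 without any 1 of the other 6 Slc6a2 TRAP arrays, and 0 without the PBS female or the LPS male of either batch in Slc6a4 TRAP. No probe passed for an LPS response that differed between the sexes in Slc6a2 TRAP (limma, 2037 at an unadjusted p under 0.05, with 10% of simulated changes of 2 log2 units recovered). Without the PBS male of batch 1, 12 did, 5 without the PBS male of batch 2 and 2 without the PBS female of batch 1.

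In Slc6a4 TRAP 0 of 21863 probes passed for LPS with limma, and 204 had an unadjusted p under 0.05, against a mean of 514 in simulated data with no change. ILMN_2677859 stood at 9.88 ± 0.41 after LPS (SD, n = 4) and 5.98 ± 0.68 after PBS (SD, n = 3, 2 detected), a difference of 3.91 log2 units (SE 0.50, limma adjusted p = 0.16). ILMN_1214408 had a difference of 1.00 (SE 0.16) and ILMN_1239627 one of -1.16 (SE 0.30). ILMN_2674284 stood at 8.79 ± 0.12 after LPS (SD, n = 4) and 9.81 ± 0.11 after PBS (SD, n = 3). The limma adjusted p was 0.60 for ILMN_1214408 and 1 for the other two. With the line fitted alone, ILMN_2677859 and ILMN_1214408 passed (adjusted p = 0.025 and 0.026), and over all alternatives their adjusted p ran from 0.00090 to 1 and from 0.019 to 1. Without the LPS female of batch 1, 1 probe passed, and within title letter B 1 did. No probe passed for an LPS response that differed between the lines (limma, 848 probes at an unadjusted p under 0.05). That test recovered 22% of simulated changes of 2 log2 units, so it does not show that the lines respond alike. Without the Slc6a2 TRAP array of the PBS male in batch 1, the PBS female in batch 1 or the LPS male in batch 2, 1 probe passed.

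In total RNA 18 probes were higher and 1 lower after LPS, of 24914. ILMN_2763245 was higher by 3.04 log2 units (SE 0.47, adjusted p = 0.037), with 2.63 in batch 1 and 3.24 in batch 2, and was detected on 5 of 8 PBS arrays. ILMN_2649671, detected on 1 of 8 PBS arrays, was higher by 2.31 (SE 0.34). ILMN_1241293 fell by 1.06 (SE 0.16). Of the 18 of these 19 probes tested in TRAP, 17 had the same sign in Slc6a2 TRAP and 14 in Slc6a4 TRAP. Adjusted over the list alone, 11 passed in Slc6a2 TRAP and 0 in Slc6a4 TRAP, in tests whose shared spread can favour Slc6a2. With each line fitted alone, 9 of 14 tested passed in Slc6a2 TRAP and 0 of 9 in Slc6a4 TRAP (limma, 3 at an unadjusted p under 0.05). Among the Slc6a4 TRAP arrays labelled LPS, that of the female in batch 1 lay at 0.21 between the PBS (0) and the LPS mean (1). The others lay from 0.89 to 0.99. The list was not tested without that array, so these counts do not show a difference between the lines. TRAP and total RNA were taken to be from the same mice, so these tests are not independent of the list. No probe passed for an LPS response that differed between TRAP and total RNA (limma, 1088 probes at an unadjusted p under 0.05, with 68% of simulated changes of 2 log2 units recovered). Without 1 TRAP array there were 4 (Slc6a2 PBS male of batch 1), 2 (Slc6a4 PBS male of batch 2) or 1 (Slc6a2 PBS female of batch 1). The count of 19 for total RNA was 122 without the array labelled LPS of the Slc6a4 female in batch 1, 74 without the Slc6a2 PBS male of batch 1, 58 without the array labelled PBS of the Slc6a2 male in batch 2 and 37 without the Slc6a4 LPS male of batch 2. It was 1 without the Slc6a2 LPS female of batch 2, and 0 without the Slc6a2 PBS female of batch 2, LPS female of batch 1 or LPS male of batch 2, or the Slc6a4 PBS female or PBS male of either batch or LPS male of batch 1. It was 35 with the title letter as a random block, 2 with the letter as a term in the additive model, 0 within letter D and 4 within letter E.

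Each array was placed between the PBS mean (0) and the LPS mean (1) of its fraction, on 20 probes chosen without the arrays of its own mouse. Of 15 TRAP arrays 14 lay on the side of their label, and of 15 total RNA arrays 13 did. The exceptions were the Slc6a4 female labelled LPS in batch 1, at 0.21 in TRAP and 0.065 in total RNA, and the Slc6a2 male labelled PBS in batch 2, at 0.75 in total RNA. For sex, the same kind of score placed 15 of 15 total RNA arrays and 14 of 15 TRAP arrays on the side of their label. The exception was the Slc6a2 TRAP array of the LPS male in batch 1, at 0.60 between the male (0) and the female mean (1), with the female Slc6a2 TRAP arrays from 0.62 to 0.95. ILMN_1215914 was at 8.92 on it, and without this array 1 probe passed for sex in Slc6a2 TRAP.

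**Figure D3:**
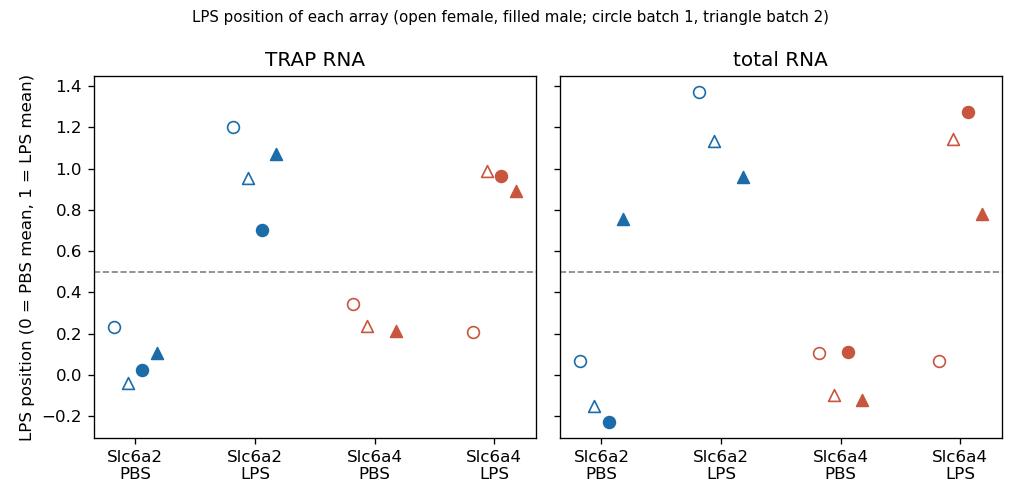
LPS position of each array (0 is the PBS mean and 1 the LPS mean of the fraction) by line and treatment, for TRAP and total RNA, with open points for females, filled points for males, circles for batch 1, triangles for batch 2 and a dashed line at the midpoint. 14 of 15 TRAP arrays and 13 of 15 total RNA arrays lie on the side of their label.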

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

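The tests of the doubtful arrays, of the probes high in batch 1 and of the correlation between batches, and the look at the title letter, were chosen after the results were seen. The simulation and the counts of other splits were set out before their results were seen. Of 76 groups of 4 to 10 arrays examined for a value far from the others, 7 had one, where chance gives about 5%.

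In total RNA the array labelled PBS of the Slc6a2 male in batch 2 lay nearer the LPS level (position 0.75). The array labelled LPS of the Slc6a4 female in batch 1 lay near the PBS level, where ILMN_2649671 was 5.56 against 7.06 to 8.19 on the other LPS arrays. For the Slc6a2 male, the TRAP array taken to be of the same mouse had a position of 0.11, which argues against a mouse in the LPS state. That TRAP array stood apart from its set and had the fewest probes detected, so this argument is weak. The total RNA array labelled LPS of that line and sex, at 0.96, argues against a swap between it and the doubtful array. For the Slc6a4 female, the TRAP array had a position of 0.21, with the other LPS arrays of that set from 0.89 to 0.99, so a mouse that responded little is consistent with both arrays. The 4 probes the report names for LPS in Slc6a4 TRAP run the way of the label on that TRAP array, each beyond all arrays after PBS (ILMN_2677859 at 9.32 against 5.23 to 6.56, ILMN_1214408 at 12.24 against 11.08 to 11.39, ILMN_2674284 at 8.79 against 9.71 to 9.92 and ILMN_1239627 at 8.32 against 8.57 to 9.52). They were chosen with this array among those after LPS, which favours such an order. Without it they ranked 2, 3, 41 and 182 by p, and of the 20 first 5 lay nearer the LPS mean on it. RNA of a mouse without LPS cannot be told apart from it by 20 probes chosen in the other Slc6a4 TRAP arrays: the array had a position of 0.32, while left-out PBS arrays ran from 0.46 to 0.73 and another LPS array was at 0.42, so this score does not separate the treatments. A swap with a total RNA array labelled PBS of that line and sex is argued against by the highest position among those, 0.11. A swap with any other total RNA array of the series needs a partner out of place, and the lowest other position with the LPS label was 0.78 and the highest other with the PBS label 0.11. An exchange of both arrays with each other is argued against by their sex, at -0.012 for the male and 0.95 for the female between the male (0) and female mean (1). For the Slc6a4 female, an exchange of the whole mouse or of its TRAP array is argued against by the highest position of a TRAP array labelled PBS, 0.34. A single wrong label, a swap with a sample from outside the series, an injection of PBS in place of LPS and, for the Slc6a2 male, an error in the pairing by mouse stay open.

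Among probes kept in TRAP, 46 were on average over 3 log2 units higher in batch 1 than in batch 2 of Slc6a2 TRAP, with no overlap. Chosen on Slc6a2 arrays alone, they differed in Slc6a4 TRAP by a median of 2.20 log2 units (quartiles 1.57 and 4.08), so a difference in the precipitated RNA between the batches of both lines may underlie them. In total RNA the median was -0.062, which argues against an amplification batch that acts on all RNA, though total RNA of batch 1 was Pre-IP and of batch 2 Unbound. Of the 46 probes, 32 were called higher in Slc6a2 TRAP than in total RNA. No biological explanation was tested.

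The 2268 probes with an unadjusted p under 0.05 for sex in Slc6a2 TRAP may in part come from the pooled estimate of the spread. Simulated data with no sex difference and the spread of each line held a mean of 1738 such probes, against 1093 expected with equal spread. The highest of 20 simulations was 1824. For LPS the same simulations held a mean of 1727 in Slc6a2 TRAP, where 2262 were observed. In Slc6a4 TRAP they held a mean of 508 for sex and 514 for LPS, where 90 and 204 were observed, below the lowest simulations (456 and 470). The simulated range therefore sets no limit, and whether the unequal spread accounts for all of the observed number stays open. Sex differences of many transcripts cannot be told apart from chance here: the correlation between batches was 0.027. The other pairings of arrays were each counted with both signs, which gave 16 values. The largest in size, 0.035, is the LPS contrast of the same arrays. Pairings that set different contrasts against each other (12 values with both signs) ran up to 0.031 in size.

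The other values far from their group were these. The Slc6a2 total RNA array of the LPS male in batch 2 had a median intensity of 148.2, with the others from 100.4 to 112.8; its title has the letter F, whose 3 arrays ran from 121.9 to 148.2, and the others have the letter D. ILMN_2580825 was at 7.89 on the Slc6a2 TRAP array of the LPS female in batch 1, with the others up to 4.87. ILMN_2729817 was at 7.11 on that of the LPS male in batch 2, with the others up to 5.44. ILMN_2726905 was at 9.99 on that of the PBS female in batch 1, with the other females from 10.86. ILMN_1235995 was at 7.76 on the Slc6a2 total RNA array of the PBS male in batch 2, with the other males from 8.69.

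Other splits of the same arrays into groups of the same sizes were counted in a simpler model of the split and the batch, in which the counts differ from those of the report. Chance can be excluded for TRAP against total RNA in the Slc6a2 line (10703 probes, 1 of 100 splits as many, highest other 8808, a split that misplaces 1 array) and in the Slc6a4 line (12078, 1 of 100, highest other 0). It can be excluded between the lines (2606, 1 of 100, highest other 534, a split that misplaces 2 arrays) and for sex in total RNA (9, 1 of 100, highest other 8, a split that misplaces 1 array). For LPS in total RNA no other split called as many (74, 1 of 100, highest other 3). Its count in the report was 19, and it fell to 0 without any 1 of several arrays, so chance is not excluded for it. Where 100 splits were counted, the true one among them, 6435 were possible. For LPS in Slc6a2 TRAP no other split called as many (5, 1 of 35, highest other 3). That is the smallest share 35 splits can give, and several comparisons were tried. The count in the report was 0 with array weights or with the line fitted alone, so chance is not excluded there. These splits do not test the letter in the sample titles, with which the fraction goes throughout and the line except within letters C and F. Chance cannot be excluded for the number of probes by sex in Slc6a2 TRAP (2, 5 of 35, highest other 5, the split by treatment), by sex in Slc6a4 TRAP (3, 2 of 35, highest other 3) or by LPS in Slc6a4 TRAP (1, 4 of 35, highest other 3, the split by sex).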

How the results depend on the processing

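Of the alternatives below, the quantile step on the log2 scale, each line fitted alone (the lists from total RNA included), all uses of the title letter and the fit without the arrays in doubt were chosen after the data were seen. The fit without the arrays in doubt picks arrays by the outcome, so its counts lean upward. Of 188 counts under alternatives other than leaving out an array, 122 stayed within 1.5 times and 66 did not. A count within 1.5 times can hold other probes: for sex in Slc6a2 TRAP, detection on every array of a fraction and enriched probes only each gave 1 higher and 0 lower in females, against 0 and 1, with 0 probes shared. No named probe reversed its sign: of their alternative values 1578 kept their direction and side of the threshold or stayed within 1 SD, 175 lost the call, 41 gained it and 8, within a batch, moved by more than 1 SD. Called probes were named only where both batches had the same sign, which largely fixed the sign of their single-batch values. The other alternatives refit all or part of the same arrays, so the lack of reversals says little. The cause of the shifts below was not tested, except that single batches, single letters and left-out arrays give fewer samples.

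For sex in Slc6a2 TRAP (1 probe) the count was 3 with median centring, 0 with array weights, 2 in the additive model, 350 with a spread shared by all 30 arrays and 0 with the line alone. For sex in Slc6a4 TRAP (2 probes) it was 1 without normexp, with median centring, with TRAP and total RNA normalised separately and without a probe filter, 0 with detection on every array of a fraction, with enriched probes only and with the line alone, and 4 with the shared spread. For sex in total RNA (8 probes) it was 0 with detection on every array, a filter that removes probes undetected in 1 sex. For LPS in Slc6a2 TRAP (16 probes) it was 28 without normexp, 27 with separate normalisation, 27 with the quantile step on the log2 scale, 4 without a filter, 0 with weights, 459 with the shared spread, 3 with enriched probes only and 0 with the line alone. For LPS in Slc6a4 TRAP (0 probes, limma, 204 at an unadjusted p under 0.05) it was 1 without normexp, with separate normalisation, without a filter, in the additive model, with the shared spread, with enriched probes only and without the arrays in doubt, and 2 with weights and with the line alone. For LPS in total RNA (19 probes) it was 10 without normexp, 38 with median centring, 3 without a filter, 44 with weights, 73 in the additive model, 4 with the shared spread and 195 without the arrays in doubt. The sex difference between TRAP and total RNA in the Slc6a2 line (0 probes, limma, 1734 at an unadjusted p under 0.05) gave 2 with median centring and with separate normalisation and 1 without a filter. The LPS response between TRAP and total RNA (0 probes, limma, 1088 at an unadjusted p under 0.05) gave 1 without normexp and in the additive model and 2 with detection on every array.

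TRAP against total RNA gave 2349 probes in the Slc6a2 line and 2689 in the Slc6a4 line in batch 1 alone, against 11393 and 10990 in both batches. The lines differed in 72 probes in batch 1 alone, 988 in batch 2 alone and 3811 with the shared spread, against 1878. Separate normalisation turned 5164 higher and 6229 lower probes into 2605 and 11782 in the Slc6a2 line, and 5411 and 5579 into 2686 and 11050 in the Slc6a4 line. Median centring gave 4323 higher and 8044 lower in the Slc6a2 line. Without the probe filter there were 7255 higher and 6078 lower in the Slc6a2 line, and 6543 and 5310 in the Slc6a4 line. Between the lines, 44 were higher and 28 lower in batch 1 alone, against 750 and 1128.

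The letter in the sample titles, possibly the slide, had a correlation of -0.024 as a random block over all arrays, -0.021 in TRAP and -0.12 in total RNA. As a random block it gave 35 probes for LPS in total RNA, and no other count moved by over 1.5 times (2163 between the lines, 12092 and 11714 for TRAP against total RNA). As a term it gave 54 between the lines, 0 for sex in Slc6a2 TRAP, 0 for sex in Slc6a4 TRAP and 0 for LPS in Slc6a2 TRAP (limma, 2175, 106 and 2185 at an unadjusted p under 0.05). In the additive model with the letter, total RNA gave 7 for sex and 2 for LPS. Within letter C the lines differed in 86 probes. On simulated changes of 2 log2 units both fits of the lines recovered 0%, and those within letters A and B at most 4.5%, so a count of 0 there says little. Within letter A there were 0 for sex and 0 for LPS in Slc6a2 TRAP (limma, 1215 and 725 at an unadjusted p under 0.05), and within letter B 0 for sex (774) and 1 for LPS in Slc6a4 TRAP. Within letters D and E of total RNA there were 0 and 3 for sex and 0 and 4 for LPS (limma, 1566 and 1107 at an unadjusted p under 0.05 within D). With a line fitted alone, TRAP against total RNA gave 8210 probes in the Slc6a2 line and 13994 in the Slc6a4 line.

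With no replicate block, that is without the batch term, the counts were 10468 and 9990 for TRAP against total RNA in the Slc6a2 and Slc6a4 line, 1626 between the lines, 3 and 2 for sex in Slc6a2 and Slc6a4 TRAP, 7 for sex in total RNA, 12 and 0 for LPS in both TRAP sets and 10 for LPS in total RNA. The differences of differences stayed at 0 (limma, 848 to 2037 at an unadjusted p under 0.05 with the block). With the mouse as a random block, TRAP against total RNA gave 11646 and 11291.

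Leaving out each array in turn gave 10153 to 12216 probes for TRAP against total RNA in the Slc6a2 line, 9627 to 11880 in the Slc6a4 line and 1154 to 2450 between the lines. For sex it gave 0 to 61 in Slc6a2 TRAP, 0 to 3 in Slc6a4 TRAP and 7 to 17 in total RNA. For LPS it gave 0 to 51 in Slc6a2 TRAP, 0 to 1 in Slc6a4 TRAP and 0 to 122 in total RNA. The sex difference between the lines gave 0 to 2, the LPS response between the lines 0 to 1, the LPS response between the sexes 0 to 12, the sex difference between TRAP and total RNA 0 to 37 and the LPS response between TRAP and total RNA 0 to 4.

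No letter held both TRAP and total RNA, so that comparison has no value within a letter. Tests of gene lists were not run because probes are unnamed, and testing all probes separately is what was done throughout. Signal over background limits what can be called for the 14692 probes detected on no array.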

Other observations

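ILMN_2677859, singled out after its values were seen, lay between 9.32 and 10.28 on the 4 Slc6a4 TRAP arrays after LPS and between 5.23 and 6.56 on the 3 after PBS. In Slc6a2 TRAP it was at most 5.70 after LPS, and in total RNA at most 5.82 after LPS. The difference between the lines in its response was not among those that passed in limma. It was high on the Slc6a4 TRAP array of the LPS female in batch 1 as well, the array whose LPS position was 0.21.

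The batch term alone called 77 probes higher in batch 1 and 11 higher in batch 2 of TRAP. In total RNA, where it also separates Pre-IP from Unbound, it called 2067 higher in batch 1 and 1435 higher in batch 2.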
